A study of Mus musculus with 4 samples.

How the data were processed

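Messenger RNA was profiled in 4 libraries of RAW264.7 cells, a mouse macrophage line, 2 kept alone (mock) and 2 cocultured with CT26 cells, a mouse colon carcinoma line. Per the labels' protocols, the libraries were made with the Vazyme VAHTS mRNA-seq v2 kit for Illumina sequencing, RAW264.7 cells were grown in DMEM, and CT26 cells in RPMI1640. How long the cells shared a culture, in which medium, and how the macrophages were parted from the CT26 cells are not given in the sources used here.

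The values are FPKM (fragments per kilobase of gene, scaled to a library's total), deposited by the authors in 2 tables, 1 per replicate number, each with 1 mock and 1 coculture library. Per the submitters' processing notes, Trim Galore, Subread and featureCounts were used, and the genome build was named as hg38, a human build, although the gene symbols in both tables are mouse symbols. The versions, the annotation, and the gene lengths and totals behind the FPKM are not given in the sources used here. Per the file headers and row names, the tables differ in annotation: the first has 23427 rows and full decimals, the second 25239 rows and values rounded to 3 decimals. In the first table, 23 rows without a name held at most 5.2e-06% of a library's FPKM. A further 106 repeated names on 287 rows held at most 1.07%. Both kinds of row were left out. Names found once in each table gave 22554 genes.

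The FPKM were used as deposited, with no further scaling. Genes with at least 1 FPKM in at least 2 of the 4 libraries were kept, which left 10202. The values were transformed to log2(FPKM + 1), so every log2 difference is on that scale and understates the change of low genes. FPKM are not counts, so no count model was used. Coculture was compared with mock in limma 3.58.1 (R 4.3.3; lmFit and eBayes with a trended prior variance, two-sided), with the replicate pair as a block, because the 2 tables may have been normalized separately and only differences within a table are comparable. This fit has 1 residual degree of freedom and a prior of 3.43. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each value after ± is limma's moderated standard error, which borrows spread across genes, so it is not the spread of the 2 pairs. The libraries of a pair also deviated together: the correlation across genes of their deviations from the group means was 0.76. Whether the replicates are separate cultures is not stated in the labels, so the gene p-values measure only the spread between these libraries, which may be technical. Each gene was also counted when it differed at least 2-fold in the same direction in both pairs, with no test, beside the number that differed 2-fold in opposite directions.

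A total of 35 gene lists were fixed before the data were examined. They cover classically and alternatively activated macrophage genes, tumour-associated and lipid-associated macrophage genes, type I interferon and interferon gamma responses, NF-kappaB targets, chemokines and their receptors, MHC class I and class II presentation, checkpoint ligands and inhibitory receptors, phagocytosis receptors, lysosomal genes, cholesterol biosynthesis, lipid handling, glycolysis, hypoxia, oxidative phosphorylation, the amino acid (ATF4) response, the unfolded protein response, NRF2 targets, S phase, G2 and M phase, p53 targets, matrix-degrading enzymes, angiogenic and growth factors, immediate early genes, osteoclast genes, macrophage identity, epithelial, mesenchymal, lymphoid and granulocyte markers, mitochondrially encoded genes, ribosomal protein genes and heat shock chaperones. Lists with at least 3 tested members, 31 in all, were tested with limma's camera at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. At this preset, members count as nearly independent, so a list p-value rests on spread across genes and not on spread between the pairs. Camera with an estimated correlation and fry were alternatives. Members were also adjusted over their own list alone, with no correction over the 35 lists, so those counts carry no error rate over all lists. With 1 residual degree of freedom, the estimated correlation left every adjusted p at 0.65 or above, so that test called no list. Its power and that of fry were not simulated. The genes named were fixed by rule before the data were examined: among genes with a mean of at least 2 FPKM and no predicted or clone-based symbol, the 12 largest rises and falls past the test with the same sign in both pairs, filled up to 12 with genes not past the test ranked by the smaller of their within-pair differences; up to 4 members per list with the largest difference of the same sign in both pairs; and Nos2, Arg1, Mrc1, Cd274, Adgre1, Csf1r, Epcam, Krt8, Krt18, Col1a1, Sparc and Cav1. Genes outside this rule are given as chosen after their values were seen.

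The alternatives covered pseudocounts of 0.1 and 0.5, no filter or at least 5 FPKM, rescaling to a common total, median centring and quantile normalization. They also covered no block, no trended variance, robust variance, an adjusted p under 0.10, a 1.5-fold bound, and each pair left out. Each library was left out without the block, so that the lone library is assumed to vary like the other group. Such a fit compares across the 2 tables, so the table difference enters the coculture difference. Name matching through RefSeq synonyms (22661 shared genes) and a run without small RNA genes were added after the data were seen.

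The tables hold no counts, so depth was estimated from the lowest FPKM step, taken as 1 read, and the exon length of each gene in GENCODE M21, with a tolerance of 2%. This gave 15400000 reads for mock 1, 15800000 for mock 2, 16200000 for coculture 1 and 12200000 for coculture 2, each from 202 to 210 genes at the step. The ratio of low values within the first table, which needs no lengths, put coculture 1 at 1.06 times mock 1. At these depths, 1 FPKM in a gene of 2 kb is 24.5 to 32.5 reads, which limits precision near the filter. Genes with near-identical copies, such as Bcl2a1a, the MHC class I genes and ribosomal protein genes, have uncertain values because the handling of shared reads is not stated. No coordinates are given, since the tables hold none.

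The fits were tested on simulated data for the 10202 genes in this design. Variances came from limma's fitted prior, genes were independent and normally distributed, and changes were placed in genes with a mean log2(FPKM + 1) above 2. The shares below hold for that model only. With 50 changed genes per size, 0% of 1.5-fold, 14% of 2-fold, 96% of 4-fold and 96% of 8-fold changes were called, and 10 unchanged genes were called beside them. With no change simulated, 0 genes were called. A list raised by 0.5 was called and 0 of 20 unchanged lists were. Members of these lists moved independently, which members of real lists may not, so this gives no rate of false list calls. The estimated correlation (0.46 for NF-kappaB genes) does not measure this. With 1 residual degree of freedom it reflects only how many members had the higher difference in pair 1. Depth and figures were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.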

Results

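The series profiled RAW264.7 mouse macrophages grown with or without tumour cells, here the mouse colon carcinoma line CT26. It holds 2 mock and 2 coculture libraries. Replicate 1 of each group forms pair 1 and replicate 2 forms pair 2, each pair in a table of its own. The estimated depth was 12200000 to 16200000 reads per library, and 9927 to 10084 genes reached 1 FPKM. The 10 most abundant genes took 9.05% and 6.94% of the FPKM in mock 1 and 2, and 9.56% and 10.1% in coculture 1 and 2. Differences are coculture minus mock on the log2(FPKM + 1) scale, and adjusted p-values are Benjamini-Hochberg values from limma with the pair as a block.

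The 3 largest rises past the test in cocultured macrophages were in the cytokine and chemokine genes Cxcl2, Il1b and Csf3. Cxcl2, a chemokine that attracts neutrophils, rose by 7.54 ± 0.51 (limma's moderated SE, n = 2 pairs, limma adjusted p = 0.04995). Its difference was 8.59 in pair 1 and 6.48 in pair 2. It went from 2.47 to 1338 FPKM in pair 1 and from 0.644 to 146 FPKM in pair 2. Il1b, which encodes interleukin-1 beta, rose by 6.66 ± 0.32 (limma adjusted p = 0.027), from 0.0981 to 72.3 FPKM and from 0.188 to 180 FPKM. Csf3, the granulocyte colony-stimulating factor gene, rose by 6.07 ± 0.15 (limma adjusted p = 0.00771), from 0.0956 to 74.9 FPKM in pair 1 and from a listed 0 to 64.4 FPKM in pair 2. Ccl3, another chemokine gene, rose by 2.94 ± 0.14 (limma adjusted p = 0.027), from 75.7 to 649 FPKM and from 160 to 1122 FPKM. The early response gene Ier3 rose by 4.05 ± 0.21, reaching 639 and 654 FPKM.

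Nfkbiz, an atypical inhibitor of NF-kappaB, rose by 3.23 ± 0.21 (limma adjusted p = 0.04995) and Socs3, a feedback inhibitor of cytokine signalling, by 2.94 ± 0.12 (limma adjusted p = 0.027). The transcription factor genes Pou2f2 and Jdp2 both rose by 2.23, with SE of 0.14 and 0.12. Clec4e, a pattern recognition receptor gene, rose by 2.03 ± 0.12, from 96.0 to 423 FPKM in pair 1 and from 25.0 to 98.9 FPKM in pair 2. Tmem171 rose by 2.43 ± 0.15 and Ehd1, an endocytic recycling gene, by 2.31 ± 0.11. Glrx, the glutaredoxin gene, chosen after its values were seen, rose by 1.68 ± 0.11 and completed the 13 genes called. Of these, 5 (Cxcl2, Nfkbiz, Tmem171, Pou2f2 and Glrx) had a limma adjusted p of 0.04995, just under the bound.

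**Figure D1:**
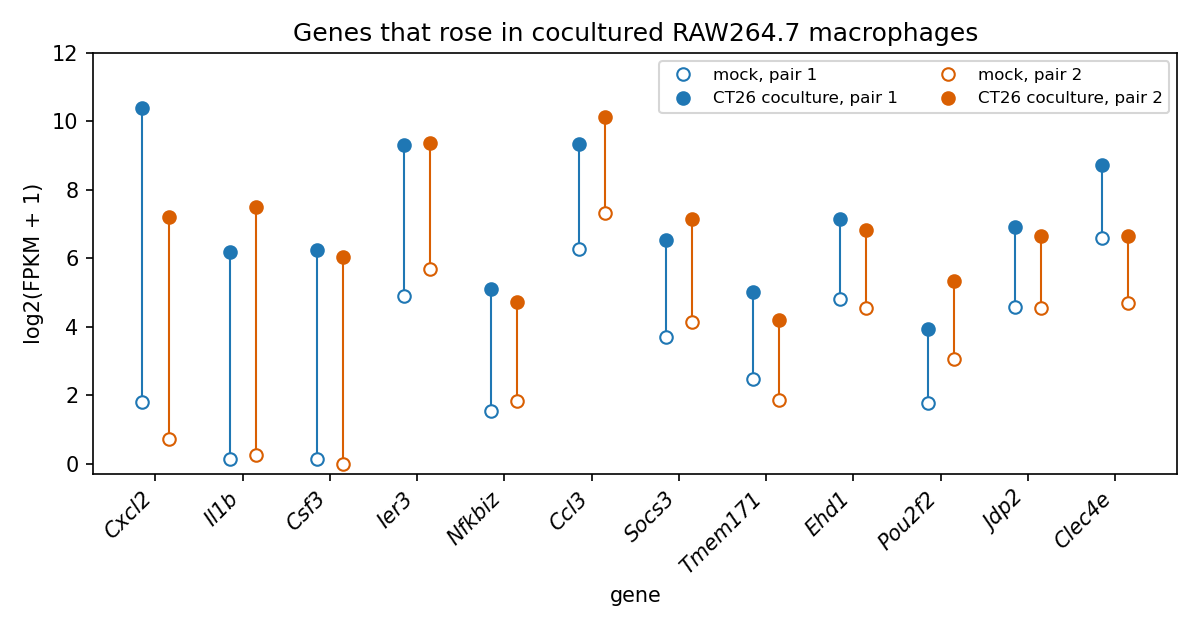
Levels of the 12 genes with the largest rises past the test, as log2(FPKM + 1) on the vertical axis, in mock (open points) and CT26 coculture (filled points) libraries of pair 1 (blue) and pair 2 (orange). Lines join the libraries of a pair. The coculture library lies above the mock library in both pairs of each gene, by 7.54 on average for Cxcl2 and by 2.03 for Clec4e.

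No gene passed the test in the other direction. Usp2, a deubiquitinase gene, stood at 7.53 and 9.61 FPKM in mock and at 1.25 and 2.05 FPKM in coculture, a difference of -1.86 ± 0.17 (limma adjusted p = 0.062). Gpr183, an oxysterol receptor gene, differed by -1.41 ± 0.12 (limma adjusted p = 0.059), and Tfeb, a regulator of lysosomal genes, by -1.27 ± 0.15 (limma adjusted p = 0.096). The other genes with the largest lower values in both pairs were Fgd4, Htr1b, Frmd4b, Fhod1, Calhm2, Susd3, Tmem51, Lpar5 and Rab3il1, with differences from -1.92 to -1.23.

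Of the 10202 genes tested, 13 rose and 0 fell in limma, while 537 were higher and 964 lower at an unadjusted p under 0.05. Without the pair block limma called 1 gene, Csf3, with no filter on low values it called 0 (1620 at an unadjusted p under 0.05), and without any single library, also unblocked, it called 0 (176 to 523). After median centring of each library the split was 85 genes up and 18 down, or 756 and 705 at an unadjusted p under 0.05, and after rescaling to a common total the latter were 448 and 1295.

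Differences of at least 2-fold in both pairs were found for 104 higher and 36 lower genes, against 7 that were 2-fold different in opposite directions. Unrelated pairs with the same numbers of 2-fold genes would share 7.47 higher and 2.81 lower genes. The split was 118 higher and 64 lower after rescaling to a common total (16 in opposite directions), 145 and 75 with a pseudocount of 0.1 (19 opposite), and 245 and 221 at a 1.5-fold bound (58 opposite). Among those higher in both pairs without passing the test were Acod1, which makes itaconate, at 6.31 ± 0.47 (limma adjusted p = 0.054), and Ptgs2, the inducible cyclooxygenase gene, at 4.63 ± 0.54 (limma adjusted p = 0.091). Tnf stood at 43.9 and 32.9 FPKM in mock and 755 and 288 FPKM in coculture (limma adjusted p = 0.054). Alone, pair 1 had 231 higher and 150 lower genes of 2-fold, and pair 2 had 330 and 191. Across the tested genes, which are not independent replicates, the differences in the pairs had Pearson's r of 0.48 and Spearman's rho of 0.37, and 63.6% had the same sign.

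NF-kappaB target genes rose as a list, with a median difference of 1.59, or 2.14 in pair 1 and 1.08 in pair 2. Of the 20 tested, 3 rose (Cxcl2, Il1b and Nfkbiz), 0 fell and 17 did not pass; adjusted over the list alone, 16 rose and 0 fell. Traf1 stood at 2.91 and 3.41 FPKM in mock and 90.3 and 19.2 FPKM in coculture. The list passed limma's camera test (adjusted p = 6.18e-21; adjusted p = 0.65 with an estimated correlation). The first of these values, like the other camera values at the preset correlation, rests on spread across genes and not between the pairs. Classically activated macrophage genes rose as a list with a median of 2.94, or 1.39 with no filter on low values (camera adjusted p = 6.54e-12; adjusted p = 0.65 with an estimated correlation). Of 9 tested, 2 rose (Il1b and Socs3), and adjusted over the list alone 8 rose, among them Acod1 and Ptgs2. Nos2, the inducible nitric oxide synthase gene, was below the filter: it stood at 0.04896 and 0.030 FPKM in mock and at 0.710 and 44.1 FPKM in coculture.

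Chemokine and receptor genes rose as a list with a median of 1.38, or 0.98 with no filter on low values (camera adjusted p = 4.83e-10; adjusted p = 0.65 with an estimated correlation). Of 13 tested, 2 rose (Cxcl2 and Ccl3) and 0 fell; adjusted over the list alone, 10 rose and 1 fell. Ccl4 stood at 14.1 and 25.7 FPKM in mock and 401 and 304 FPKM in coculture. Cx3cr1, the fractalkine receptor gene, chosen after its values were seen, was the 1 that fell over the list alone, at -0.78 ± 0.18. Angiogenic and growth factor genes rose with a median of 1.34, or 1.69 in pair 1, 0.84 in pair 2 and 0.42 with no filter on low values (camera adjusted p = 4.92e-05; adjusted p = 0.65 with an estimated correlation). Of 10 tested, Csf3 rose, and adjusted over the list alone 6 rose and 3 fell. Vegfa stood at 5.45 and 18.9 FPKM in mock and 18.6 and 61.7 FPKM in coculture (limma adjusted p = 0.054), while Igf1, Vegfb and Pdgfa, chosen after their values were seen, were those lower over the list alone. Immediate early genes rose with a median of 0.55 (camera adjusted p = 2.39e-09; adjusted p = 0.65 with an estimated correlation). Of 21 tested, Ier3 rose, and adjusted over the list alone 10 rose and 0 fell, among them Dusp5 at 3.65 ± 0.26 and Myc at 3.53 ± 0.35.

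**Figure D2:**
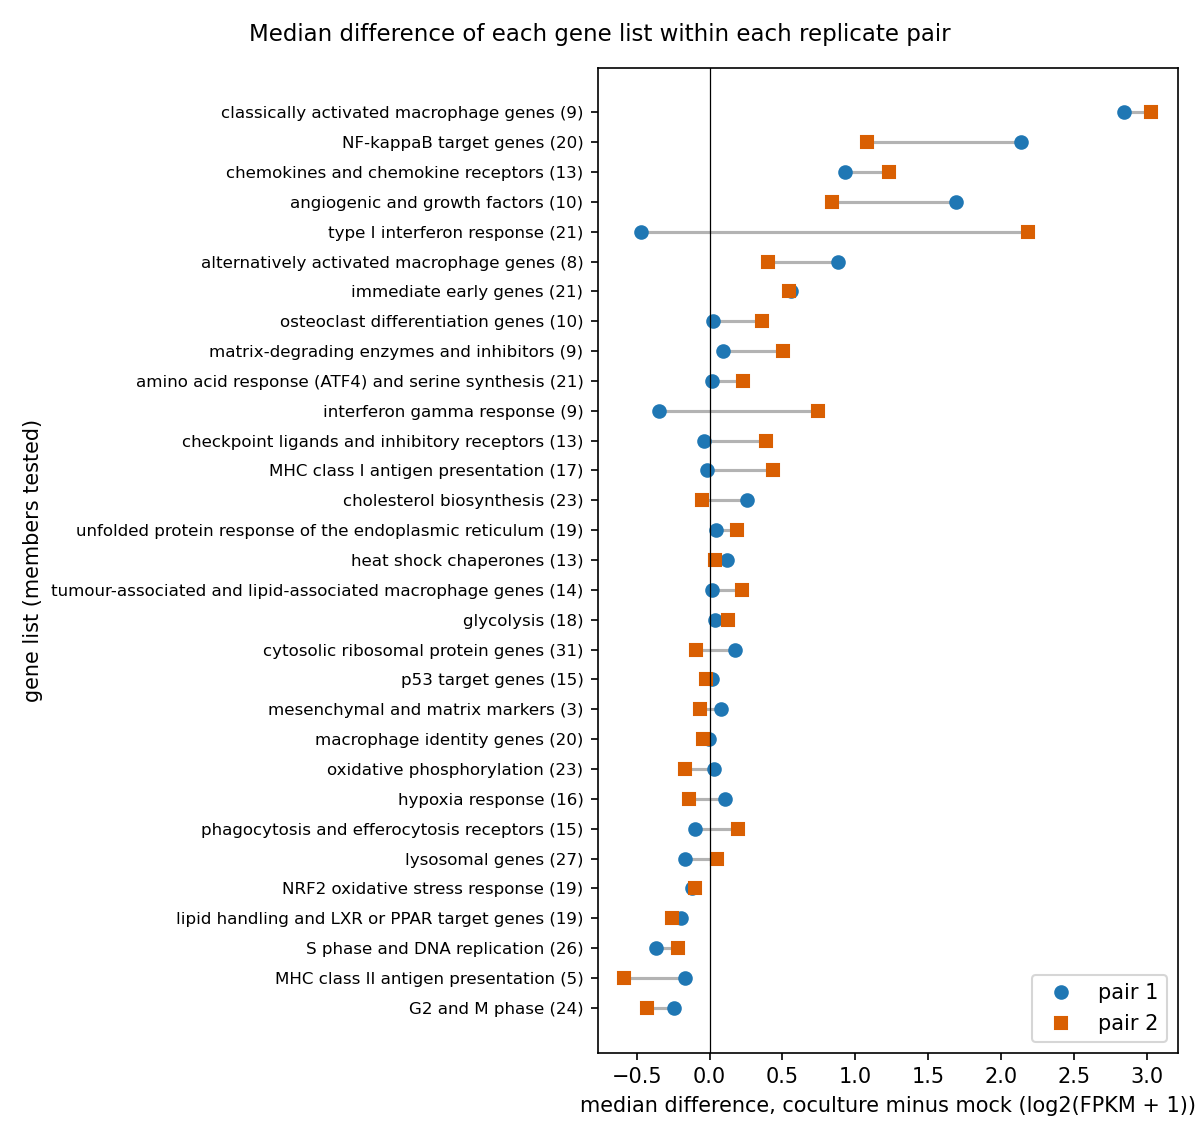
Median difference of each gene list, coculture minus mock in log2(FPKM + 1), in pair 1 (blue circles) and pair 2 (orange squares), with the number of members tested in parentheses. Classically activated macrophage genes lie at 2.85 and 3.03, and type I interferon genes at -0.47 and 2.19.

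Alternatively activated macrophage genes rose as a list, with a median of 0.61, or 0.88 in pair 1, 0.40 in pair 2 and 0.31 with no filter on low values (camera adjusted p = 0.000584; adjusted p = 0.65 with an estimated correlation). Only 8 of the 19 members reached the filter and were tested, so the list speaks for those alone. Of these, 0 passed over all genes. Adjusted over the list alone, 4 rose (Myc, Il1rn, Tgfb1 and Msr1) and 1 fell (Klf4), with Tgfb1 and Msr1 chosen after their values were seen. Myc is also a member of the immediate early list. Il1rn, which encodes the interleukin-1 receptor antagonist, stood at 12.03 and 2.76 FPKM in mock and 56.9 and 35.5 FPKM in coculture. Arg1 did not exceed 0.626 FPKM in any library, nor Mrc1 0.730 FPKM. Tumour-associated and lipid-associated macrophage genes did not pass (median 0.09, or -0.05 after quantile normalization; camera adjusted p = 0.142). None of 14 passed, and adjusted over the list alone Vegfa rose. Its members went both ways: Spp1 differed by 1.86 ± 0.69 (0.48 in pair 1 and 3.25 in pair 2) and Gpnmb by -1.78 ± 0.70 (-0.34 and -3.23).

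Checkpoint ligands and inhibitory receptors rose as a list with a median of 0.17 (camera adjusted p = 0.0381; adjusted p = 0.65 with an estimated correlation), but lay at -0.04 in pair 1 and 0.38 in pair 2, and at -0.23 without mock 1, unblocked. None of 13 passed over all genes, and adjusted over the list alone Cd274, Cd47, Lilrb4a and Pvr rose and Sirpa fell, with Cd47 and Pvr chosen after their values were seen. Cd274, which encodes PD-L1, stood at 0.429 and 0.488 FPKM in mock and 2.62 and 3.82 FPKM in coculture (limma adjusted p = 0.123). Matrix-degrading enzymes and inhibitors rose with a median of 0.26, or 0.11 with no filter on low values (camera adjusted p = 0.00340; adjusted p = 0.65 with an estimated correlation). The matrix median was 0.09 in pair 1 and 0.51 in pair 2, and the call was lost without mock 2 (adjusted p = 0.0994) or without coculture 1 (0.124), unblocked. None of 9 passed over all genes, and adjusted over the list alone 3 rose and 0 fell, among them Plaur, the urokinase receptor gene, and Timp1, which encodes an inhibitor of matrix metalloproteinases. Osteoclast differentiation genes rose with a median of 0.38, or 0.20 with no filter on low values (camera adjusted p = 0.0347; adjusted p = 0.65 with an estimated correlation). The osteoclast median was 0.02 in pair 1 and 0.36 in pair 2, and the call was lost without mock 2 (median -0.01, adjusted p = 0.392) or without coculture 1 (0.228), unblocked, with at least 5 FPKM (0.0906), and after median centring (0.0566) or quantile normalization (0.0864). None of 10 passed, and adjusted over the list alone Src rose.

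Type I interferon response genes went in opposite directions in the pairs. Their median was -0.47 in pair 1 and 2.19 in pair 2, and 19 of the 21 tested differed in sign. Irf7 and Isg15 were chosen after their values were seen. Irf7, a transcription factor of the interferon response, stood at 19.4 FPKM in mock 1 and 17.1 FPKM in coculture 1, against 1.13 FPKM in mock 2 and 44.4 FPKM in coculture 2. Isg15 stood at 5.51 and 5.14 FPKM in pair 1 and at 0.252 and 18.9 FPKM in pair 2. None of the 21 rose or fell, over all genes or adjusted over the list alone. Camera called the list up (median 0.91; adjusted p = 6.60e-05; adjusted p = 0.65 with an estimated correlation), and without mock 2, unblocked, the call was lost (median -0.07, adjusted p = 0.776; range over 16 settings 1.14e-21 to 0.776). Interferon gamma response genes did not pass (median 0.20, or -0.34 in pair 1 and 0.74 in pair 2; camera adjusted p = 0.116), with 0 of 9 past the test and Cd274 and Cxcl10 up when adjusted over the list alone. The interferon gamma list was called up without the pair block (adjusted p = 0.0378) and with no filter on low values (0.0220). MHC class I presentation genes rose as a list with a median of 0.17 (camera adjusted p = 0.0137; adjusted p = 0.65 with an estimated correlation), but lay at -0.01 in pair 1 and 0.43 in pair 2. None of 17 passed over all genes or adjusted over the list alone.

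**Figure D3:**
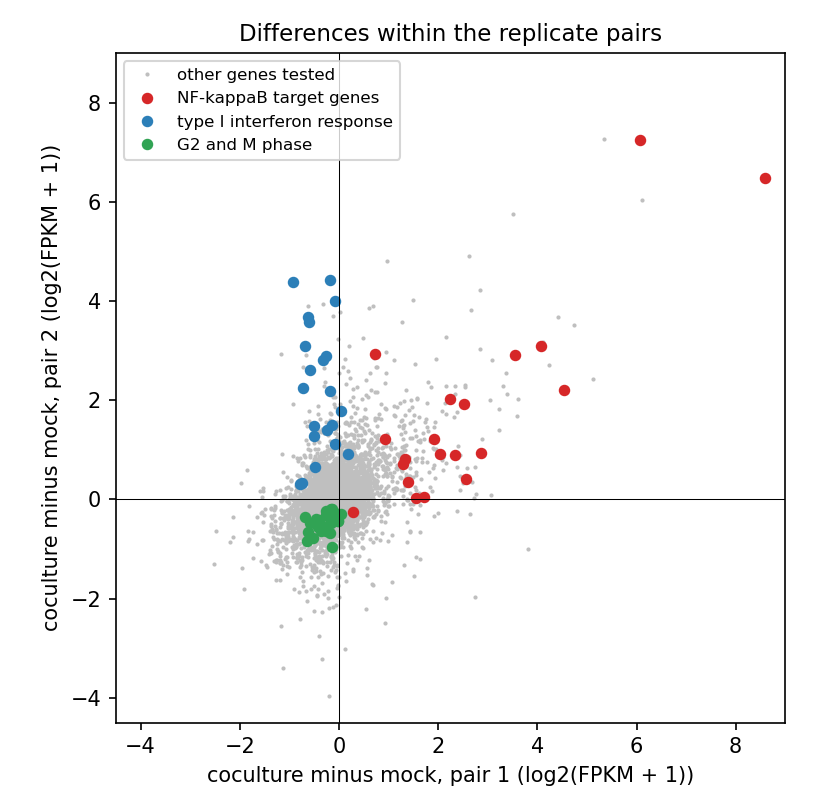
Coculture minus mock in pair 1 (horizontal axis) and pair 2 (vertical axis), in log2(FPKM + 1), for each of 10202 genes tested (grey), with NF-kappaB target genes (red), type I interferon response genes (blue) and G2 and M phase genes (green). Of the NF-kappaB genes 19 of 20 are higher in both pairs, of the interferon genes 19 of 21 differ in sign, and of the G2 and M phase genes 23 of 24 are lower in both.

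Cell cycle genes were slightly lower in cocultured macrophages. G2 and M phase genes fell as a list, with a median of -0.39, or -0.24 in pair 1 and -0.43 in pair 2, and 23 of 24 were lower in both pairs (camera adjusted p = 2.41e-07; adjusted p = 0.65 with an estimated correlation). None fell over all genes; adjusted over the list alone, 9 fell, among them Mki67, the Ki-67 proliferation marker, at -0.74 ± 0.12, Kif11 at -0.65 ± 0.13 and Cenpf at -0.64 ± 0.13. S phase and DNA replication genes fell as a list, with a median of -0.30 (-0.37 in pair 1 and -0.21 in pair 2) and 20 of 26 lower in both pairs (camera adjusted p = 9.27e-05; adjusted p = 0.65 with an estimated correlation). None of them passed over all genes or adjusted over the list alone; Dtl differed by -0.66 ± 0.20 and Cdt1 by -0.52 ± 0.16. Without mock 1 or without coculture 2, unblocked, the S phase median shrank to -0.095 or -0.15 and the call was lost. p53 target genes did not pass (median 0.03, or -0.02 after rescaling to a common total; camera adjusted p = 0.181), with 0 of 15 past the test and Fas, Cdkn1a and Mdm2 (the last chosen after its values were seen) up when adjusted over the list alone.

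Among stress and metabolic lists, amino acid response (ATF4) genes rose as a list with a median of 0.20 (camera adjusted p = 0.00501; adjusted p = 0.65 with an estimated correlation), but lay at 0.02 in pair 1 and 0.23 in pair 2. Without mock 1 or without coculture 2, unblocked, the ATF4 median was -0.06 or -0.24. Of 21 tested, 0 passed, and adjusted over the list alone the cystine transporter gene Slc7a11 rose; it stood at 13.0 and 4.19 FPKM in mock and 49.3 and 24.0 FPKM in coculture. Cholesterol biosynthesis genes were called up with a median of 0.11, but lay at 0.26 in pair 1 and -0.05 in pair 2 (camera adjusted p = 0.0137; adjusted p = 0.68 with an estimated correlation), and 0 of 23 passed, adjusted over the list alone or over all genes. Unfolded protein response genes (median 0.10, or 0.04 and 0.19 in the pairs, 0 of 19 passed) and glycolysis genes (median 0.08, or 0.04 and 0.12 in the pairs, 0 of 18 passed) were called up at camera adjusted p = 0.0438 and 0.0459 (adjusted p = 0.65 with an estimated correlation for both). None of their members passed when adjusted over the list alone, and both calls were lost after rescaling to a common total, median centring or quantile normalization. The unfolded protein and glycolysis medians were 0.05 and 0.02 after rescaling, 0.17 and 0.14 after centring, and 0.11 and 0.00054 after quantile normalization. Both were also lost without the pair block (unfolded protein 0.156, glycolysis 0.0981) and with no filter (0.0990 and 0.0708), and glycolysis with at least 5 FPKM (0.0546) or without trended variance (0.0604). In the unfolded protein list Atf6 differed by -0.56 ± 0.11, Xbp1 by -0.48 ± 0.11, the chaperone gene Hspa5 by 0.39 ± 0.14 and Creld2 by 0.37 ± 0.13. In the glycolysis list the glucose transporter gene Slc2a1 differed by 0.72 ± 0.20.

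The hypoxia list did not pass (camera adjusted p = 0.305), with 0 of 16 members past the test and Vegfa up when adjusted over the list alone; its median was -0.08, its mean 0.06 and camera's direction up. The hypoxia median was 0.11 in pair 1 and -0.14 in pair 2. Without mock 2 or without coculture 1, unblocked and so across the 2 deposited tables, it was 0.76 and 0.61, and without mock 1 it was -0.68. The NRF2 list did not pass (camera adjusted p = 0.662; median -0.17, mean 0.06, direction up), with 0 of 19 past the test; adjusted over the list alone, Slc7a11 and Srxn1 rose and Gclc, a glutathione synthesis gene, fell. Lipid handling genes did not pass (median -0.20; camera adjusted p = 0.181), with 0 of 19 past the test; adjusted over the list alone, the cholesterol exporter gene Abca1 rose and Mylip and Cpt1a fell. Oxidative phosphorylation genes did not pass (median -0.05, or 0.02 after median centring, with camera's direction up; adjusted p = 0.944; 0 of 23 past the test, adjusted over the list alone or over all genes).

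Macrophage identity genes did not pass as a list (median -0.01, or 0.05 after median centring; mean 0.04; camera adjusted p = 0.391). Of 20 tested, 0 passed, and adjusted over the list alone Cd14, the lipopolysaccharide co-receptor gene, rose, from 607 to 1732 FPKM in pair 1 and from 353.9 to 1149 FPKM in pair 2. Adgre1, which encodes F4/80, differed by 0.06 ± 0.12 and Csf1r, the receptor of macrophage colony-stimulating factor, by -0.43 ± 0.13 (limma adjusted p = 0.282). Phagocytosis receptors (0 of 15 past the test; median -0.08, mean 0.0014, direction up; camera adjusted p = 0.456), lysosomal genes (0 of 27; median -0.15; camera adjusted p = 0.456) and MHC class II genes (0 of 5; median -0.36; camera adjusted p = 0.197) did not pass. Adjusted over the list alone, Tfeb and Lipa fell among the lysosomal genes and 0 passed in the other two lists.

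Of 57 epithelial and mesenchymal markers, 52 were below 1 FPKM in all libraries, and 1, Tpm1, was at least 1 FPKM higher in coculture in both pairs, at 37.7 and 43.2 FPKM in mock and 47.1 and 55.0 FPKM in coculture. S100a6, chosen after its values were seen, stood at 752 and 614 FPKM in mock and 793 and 586 FPKM in coculture. Epcam and Krt18 were listed at 0 in all 4 libraries. Krt8, Col1a1, Sparc and Cav1 reached at most 0.0683, 0.0415, 0.198 and 0.282 FPKM. The mesenchymal list, with 3 members tested, did not pass (camera adjusted p = 0.390; median 0.0047, or -0.05 after rescaling to a common total), and 0 passed when adjusted over the list alone. The epithelial, lymphoid and granulocyte lists had 1 tested member each, Pkp2 at -0.29 ± 0.19, Lck (chosen after its values were seen) at 0.27 ± 0.25 and S100a8 at 1.03 ± 0.34. None of them passed the test over all genes. S100a8 passed when adjusted over the list alone, but in a list of 1 that is its unadjusted limma p of 0.033.

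Ribosomal protein genes were called up by camera (adjusted p = 0.0459; adjusted p = 0.72 with an estimated correlation) at a median of 0.05, which was 0.18 in pair 1, -0.09 in pair 2 and -0.01 after rescaling to a common total. Of 31 tested, 0 passed, over all genes or adjusted over the list alone. Heat shock chaperones did not pass (median 0.10; camera adjusted p = 0.0907), with 0 of 13 past the test and 0 when adjusted over the list alone. The 13 mitochondrially encoded genes were named in the table of pair 1 alone and entered no test; 12 were lower in coculture 1, at a median of -0.11, and their share of the FPKM was 7.23% in mock 1 and 6.46% in coculture 1.

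In all, 18 of 31 lists passed camera, 16 up and 2 down. Lists also share members, such as Il1b, Tnf, Cxcl2 and Myc, so their calls are not independent of each other. The calls of 7 lists (classically activated, alternatively activated, NF-kappaB, chemokine, angiogenic, immediate early, and G2 and M phase genes) held in each of 16 other settings of filter, scaling, model or libraries, at adjusted p from 3.40e-37 to 0.00663, and the other 11 lost it in at least 1. Checkpoint and osteoclast genes lost it after median centring (camera adjusted p = 0.0683 and 0.0566) or quantile normalization (0.0864 for both), and with at least 5 FPKM (0.0836 and 0.0906). Checkpoint medians in these 3 settings were 0.24, 0.13 and 0.69, against 0.17 in the main fit. Those of osteoclast genes were 0.44, 0.40 and 0.38, against 0.38. MHC class I genes lost the call after quantile normalization (0.0760). Ribosomal protein genes lost it after each rescaling (0.0684 to 0.545), without the pair block (0.0981), with no filter (0.0990) and with at least 5 FPKM (0.0518). In the unblocked fits without mock 1, the checkpoint, cholesterol, glycolysis, ATF4, unfolded protein, S phase and ribosomal lists were not called (0.117 to 0.945), while interferon gamma (0.00346), heat shock (0.00569) and NRF2 genes (0.0385) were called up and MHC class II (0.0163), lipid handling (0.0322) and hypoxia genes (0.0139) down. Without mock 2, the type I interferon, MHC class I, matrix and osteoclast lists were not called (0.0994 to 0.994), and hypoxia genes were (8.13e-09). Without coculture 1, the MHC class I, matrix, osteoclast and ribosomal lists were not called (0.124 to 0.937), and interferon gamma (0.0278) and hypoxia genes (0.00276) were. Without coculture 2, the MHC class I, checkpoint, cholesterol, glycolysis, ATF4, unfolded protein and S phase lists were not called (0.166 to 0.912), and heat shock genes were (0.0270). With an estimated correlation 0 lists passed (0 at an unadjusted p under 0.05), and with fry 0 passed (5 at an unadjusted p under 0.05). The power of both tests with 1 residual degree of freedom was not simulated, so these outcomes neither uphold nor refute the calls. The fits with a library left out compare across the 2 deposited tables, so their gains and losses may reflect the table and not the coculture.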

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

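The comparison of genes named in a single table was chosen after the tables were seen. The gene comparison used names found once in each table. Names were compared without regard to case. Some genes stand in both sets under a newer and an older symbol, such as Polr1h and Znrd1. Of 30 genes considered that were named in the table of pair 1 alone, 1 was at least 2-fold higher in coculture: Ahnak2, with a log2 difference of 1.498, from 0.948 to 4.503 FPKM. Among the 10202 genes tested, 231 were 2-fold higher in pair 1, so 1 of 30 is close to that share. Of 57 genes considered that were named in the table of pair 2 alone, 0 were 2-fold higher, and 0 were 2-fold lower in either set. Ahnak2 rests on 1 library per group, so it has no replicate check. Groups of 2 libraries are too small for a test of outlying libraries.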

How the results depend on the processing

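The runs with synonym matching and without small RNA genes were chosen after the data were seen. The count of 13 called genes was 11 with a pseudocount of 0.5 and 13 with synonyms. It was 22 with a pseudocount of 0.1, 26 with at least 5 FPKM, 25 after rescaling to a common total (24 up, 1 down), 103 after median centring (85 up, 18 down), 46 after quantile normalization, 27 without small RNA genes and 81 at an adjusted p under 0.10; each of these sets held the 13 genes. It was 6 with robust variance, 1 without trended variance, and 0 with no filter, where 15027 genes were tested. Without the replicate block it was 1 (Csf3), and 0 without mock 1, mock 2, coculture 1 or coculture 2, each with fewer samples (350, 176, 403 and 523 genes at an unadjusted p under 0.05). The 140 genes with 2-fold differences in both pairs numbered 109 to 182 in 8 settings, 220 with a pseudocount of 0.1, 466 at 1.5-fold (58 in opposite directions), and 381 to 521 with a single pair, which needs 1 difference only. The correlation of 0.48 was 0.44 with a pseudocount of 0.1 or no filter, and 0.53 with at least 5 FPKM. In other camera fits 12 to 18 lists were called, among them 11 to 18 of the 18: 11 of 17 without mock 1, 11 of 12 without coculture 2 and 15 of 16 without the replicate block. The 18 list calls became 0 with an estimated correlation and 0 with fry (lowest adjusted p = 0.65 and 0.271). Classically activated genes had an estimated correlation of 0, which reflects only signs at 1 residual degree of freedom, yet also moved to 0.65. The power of these tests with 1 residual degree of freedom was not simulated, so the loss does not show whether the calls were true or false.

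Over the pairs taken singly, medians ran from -0.0497 to 0.26 for cholesterol biosynthesis, -0.0905 to 0.18 for ribosomal proteins, -0.47 to 2.19 for type I interferon, -0.0145 to 0.43 for MHC class I and -0.0371 to 0.38 for checkpoint genes, with signs turned in 1 pair. Without mock 1, unblocked, camera's direction turned for cholesterol biosynthesis (median -0.24), glycolysis (-0.21), hypoxia (-0.68) and the unfolded protein response (-0.0807), and the median alone for checkpoint (-0.23), ATF4 (-0.0605) and ribosomal genes (-0.0709). The direction also turned without coculture 2 for glycolysis (-0.24) and the unfolded protein response (-0.17), with the median alone for ATF4 (-0.24) and MHC class I genes (-0.0250), and without coculture 1 for ribosomal proteins (median 0.00927). Without mock 2 the median alone turned for type I interferon (-0.0699), MHC class I (-0.0488) and osteoclast genes (-0.00864), and after rescaling to a common total or quantile normalization for ribosomal proteins (-0.00776, -0.0209). The fits with a library left out compare across the 2 deposited tables, so a turned direction there may reflect the table. Unless a cause is given, the cause was not tested. Sign changes with no call came to 34 list values and 38 gene values. With 1 pair alone there is no residual spread, so no test of genes or lists was possible. In a gene of 2 kb, 1 FPKM is 24.5 to 32.5 reads.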

Other observations

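Except for the exchange of labels, the explanations weighed in this part and their predictions were written after the values were seen. All genes named here outside the rule were also chosen then. The median-centred fits, the fits with a library left out and the 2-fold counts used here were planned. Several genes outside the lists differed by at least 2-fold in both pairs. Lif, a cytokine gene of the interleukin-6 family, stood at 0.0645 FPKM in mock 1 and a listed 0 in mock 2, and at 36.3 and 4.41 FPKM in coculture. Odc1, the rate-limiting enzyme of polyamine synthesis, differed by 3.24 ± 0.30, from 134 to 849 FPKM in pair 1 and from 42.4 to 610 FPKM in pair 2 (limma adjusted p = 0.062). Slfn2 differed by 2.23 ± 0.18, Lcp2 by 1.51 ± 0.14 and Ets2 by 1.33 ± 0.12, with limma adjusted p of 0.059, 0.062 and 0.062.

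Some other genes, picked by inspection and not as a list, differed strongly in 1 pair. Gpr84, a receptor for medium-chain fatty acids, stood at 25.8 FPKM in mock 1 and 376 FPKM in coculture 1, but at 25.4 and 12.3 FPKM in pair 2. Nlrp3, an inflammasome sensor, stood at 22.8 and 159 FPKM in pair 1 and 23.7 and 25.6 FPKM in pair 2, and the dendritic cell marker Cd83 at 3.19 and 26.6 FPKM against 17.4 and 17.8 FPKM. In pair 2, the chemokine gene Ccl22 stood at 0.350 and 96.4 FPKM, against 0.180 and 0.715 FPKM in pair 1, and Acp5, the tartrate-resistant acid phosphatase gene, at 1.65 and 35.6 FPKM against 3.34 and 3.43 FPKM. Spp1, the osteopontin gene, stood at 993 and 9449 FPKM in pair 2 and 4155 and 5787 FPKM in pair 1. With 1 library per group and pair, the difference between pairs could not be tested.

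The first pattern weighed is the rise of inflammatory genes, with NF-kappaB list medians of 2.14 and 1.08 in the pairs. RNA of CT26 cells carried into the macrophage libraries could bring epithelial or mesenchymal transcripts. Of 57 such markers 1, Tpm1, was at least 1 FPKM higher in both pairs. No library of CT26 cells alone is in the series, so whether they express these markers was not measured here and the count cannot decide. Median centring shifts every gene of a library equally and moved the list median from 1.59 to 1.65. After centring, camera gave an adjusted p of 5.20e-20 (0.65 with an estimated correlation before centring). Over all genes the median differences were -0.09 and -0.06 in the pairs, so a uniform scaling difference is argued against. Exchanging the labels of pair 2 called 0 genes (92 at an unadjusted p under 0.05) against 13, but 2 labellings are too few for a share under 0.05. A response of the macrophages to the tumour cells, RNA carried over from CT26 cells, and a difference in medium or handling stay open as candidate explanations.

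The second pattern is the opposite direction of type I interferon genes in the pairs. Exchanged mock and coculture columns in 1 table would set most 2-fold genes in opposite directions, yet 7 were opposite and 140 the same, which argues against it. The list was higher in mock 1 than in mock 2 by a median of 1.46 (20 of 21 genes), and its median difference of coculture 1 from coculture 2 was -0.74 (3 of 21 higher in coculture 1). These levels are set across tables that may be normalized separately, but over all genes the medians of these differences were -0.04 and -0.08, and both list differences kept their direction under rescaling to a common total, median centring and quantile normalization. Each difference sets 1 library against 1, so a different interferon state of the mock cultures stays open as a hypothesis, as does a response of the coculture in pair 2. The estimated correlation of 1 does not measure how closely the genes moved together. With 1 residual degree of freedom it shows only that each tested gene had the higher difference in pair 2.

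The third pattern is the small drop of cell cycle genes. Median centring, which shifts every gene of a library equally, moved the G2 and M phase median from -0.39 to -0.33. After centring, camera gave an adjusted p of 7.49e-07 (0.65 with an estimated correlation before centring). By pair, the median moved from -0.24 to -0.14 in pair 1 and from -0.43 to -0.40 in pair 2. After rescaling to a common total it was -0.31 in pair 1 and -0.49 in pair 2, and after quantile normalization -0.26 and -0.42. The drop thus kept its direction under each scaling. Whether a scaling shift accounts for part of it depends on the scaling chosen. The S phase median was -0.23 after centring (camera adjusted p = 0.000188; adjusted p = 0.65 with an estimated correlation before centring). Before centring, the S phase median was -0.095 without mock 1 and -0.15 without coculture 2, unblocked, and the call was lost in both fits. Slower growth in coculture is a candidate explanation, and differences in cell density or medium between the cultures stay open and untested.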
